A study of Mus musculus with 6 samples.

How the data were processed

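RNA was measured in 6 libraries of mouse B cells, 3 from wild-type (WT) mice and 3 from mice lacking the A alpha scaffold subunit of protein phosphatase 2A in B cells (PP2Aa-deficient), all 8 weeks of age per the labels. The genotype label gives a floxed Ppp2r1a gene and a Cre recombinase, and the series describes the loss as specific to B cells. The labels name the spleen as the tissue and, in their protocols, a peritoneal wash as the source of the cells, and the data do not settle which holds. Libraries were made by a low-input Smart-seq2 protocol from total RNA, per the labels' protocols. Groups came from the source label of each sample. Nothing in the labels says that each library came from a separate mouse, so p-values measure the spread between these libraries.

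The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) with 1 column per library and 22815 rows, named by gene symbol. The layout of its header is that of Cuffnorm. The submitters' processing notes name BWA, TopHat2 2.0.10, Cufflinks 2.2.1 and Cuffnorm, with no role or order. The genome build, the annotation, the Cuffnorm scaling and the use of strand are not given in the sources used here. In the deposited table, 27 rows carried dates in place of gene symbols and were left out, which left 22788 genes. The 13 immunoglobulin constant region names and 28 mitochondrially encoded names fixed as lists had no row in the table used here. The deposited plate sheet of 12 wells gives the wells of these 6 libraries 6 different numbers, whose meaning is not stated, and calls the WT wells miRNA controls and the PP2Aa-deficient wells miRNA targets. These words differ from the genotype in the labels, which set the groups here, and the difference is not settled. The 6 other wells of the sheet were not analysed here.

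FPKM values leave out depth. Low values in each pair of libraries lay on steps of 1 fragment, and their most common ratio gave relative depths of 1.00, 1.76 and 1.23 for WT replicates 1 to 3 and 1.18, 0.98 and 1.15 for PP2Aa-deficient replicates 1 to 3. With transcript lengths from GENCODE M21, whose build may differ from the one the authors used, this corresponds to about 2030000, 3590000 and 2510000 fragments in WT and 2430000, 2000000 and 2340000 in PP2Aa-deficient libraries. Depth of this order leaves genes of a few FPKM on few fragments. A value of exactly 0 can be a failed estimate, since the ribosomal RNA precursor Rn45s was listed at 0 in 3 libraries. Such genes are given per library, with no mean or fold.

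Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 9425 in all. Values were taken as deposited, as log2(FPKM + 1), and tested with limma 3.58.1 in R 4.3.3 (moderated, two-sided, with a mean-variance trend), with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The 35 gene lists were fixed before the data were examined, as were the tests, the other settings and the rule for named genes. The 29 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, again with an estimated correlation, and with fry. With an estimated correlation camera also tests on the 4 residual degrees of freedom of the fit, a stricter test whatever the correlation. A call lost there is therefore not by itself a sign of correlation between members. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for summaries and figures. Tested on simulated data of 9425 genes with independent noise, of which 200 were changed, the limma step recovered 83.5% of changes of log2 1 and 100% of changes of log2 2. The changed genes were drawn from the better expressed ones, and the noise followed the moderated variances of the fit. These shares therefore do not give the share of real changes found. In the real data Pcbd2, at a log2 change of 2.28 (limma adjusted p = 0.0507), was not called.

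The rule for named genes took Ppp2r1a, up to 12 called genes of largest change per direction with a mean of at least 5 FPKM in the higher group and groups that did not overlap, up to 4 called members of each list or otherwise the member of smallest p, and, where fewer than 10 genes passed in a direction, the 10 of smallest p. Genes with Gm, Rik, Mir, Snor and Rn names, immunoglobulin and T cell receptor segments and ribosomal pseudogenes were not named by the rule. Further members of the called lists, and other genes named beyond the rule, were chosen after their values were seen. Results of some genes that the rule named or that were examined are not reported here. Overlapping and neighbouring genes were looked up in RefSeq genes of GRCm38.p6, by name only. The other settings were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, quantile normalization, median-ratio scaling, no mean-variance trend, array weights and leaving out each library in turn. Alternatives for count data were not run, since the values are not counts. A term for Xist, a term for relative depth and the test of the MHC class II list without its H2 members were added after seeing the data.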

Results

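Gene expression was compared between WT B cells and B cells deficient in PP2Aa, the A alpha scaffold subunit that holds protein phosphatase 2A together, with 3 libraries in each group. Relative depth ranged from 0.98 to 1.76, or from about 2000000 to 3590000 fragments, and between 9229 and 9332 genes reached 1 FPKM per library. Pairs of libraries correlated at r = 0.948 to 0.969 across genes within groups and at 0.948 to 0.959 between groups, where genes are not independent replicates. Xist, expressed from the inactive X chromosome, was at 65.2 FPKM in WT replicate 1 and 84.5 in PP2Aa-deficient replicate 1, and at most 0.116 in the other libraries, so each group held 1 library of this kind.

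Ppp2r1a, the gene with the floxed allele, was lower in all 3 PP2Aa-deficient libraries than in every WT library. It measured 84.9 ± 1.08 FPKM in WT and 38.6 ± 15.4 in PP2Aa-deficient B cells (SD, n = 3), which was 45.4% of WT. The PP2Aa-deficient replicates held 31.3, 56.2 and 28.2 FPKM. The log2 fold change was -1.18 (SE 0.23), with an unadjusted limma p of 0.000766 and an adjusted p of 0.168 over all genes. The value covers the whole gene, so transcript left outside the deleted part still counts. Without PP2Aa-deficient replicate 2 the unadjusted limma p was 4.81e-06 and Ppp2r1a passed over all genes.

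**Figure D1:**
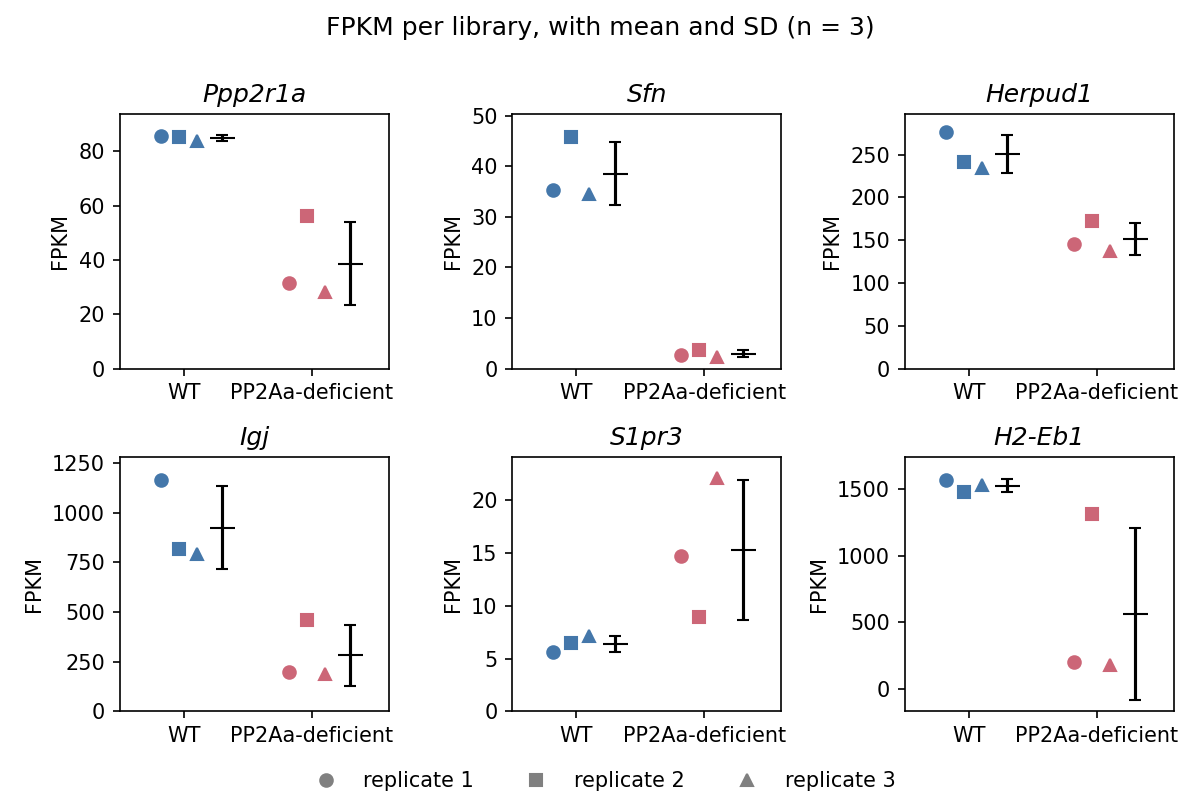
FPKM (vertical axes, linear) of Ppp2r1a, Sfn, Herpud1, Igj, S1pr3 and H2-Eb1 in WT and PP2Aa-deficient B cells, with a point per library, a symbol per replicate number that pairs nothing, and the mean and SD of 3 libraries in black. Ppp2r1a and H2-Eb1 in PP2Aa-deficient replicate 2, at 56.2 and 1313 FPKM, lay nearer to WT than in the other PP2Aa-deficient libraries.

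The search for genes that differed between the groups found 3 lower genes and 0 higher genes in PP2Aa-deficient B cells. Sfn, which encodes the 14-3-3 sigma adaptor protein, fell from 38.6 ± 6.24 FPKM in WT to 2.91 ± 0.714 (SD, n = 3), a log2 change of -3.34 (SE 0.19) and 7.5% of WT, with a limma adjusted p of 0.000432. Rab26os, a transcript from the strand opposite Rab26, was listed at 14.8, 7.48 and 12.4 FPKM in WT and at 0 in every PP2Aa-deficient library (limma adjusted p = 0.00145), while Rab26 itself did not exceed 0.428 in any library. Rab26os lies on the same chromosome as Ppp2r1a, as do Tmem242 and Tagap1. Sfn and Sh3bgrl3 are neighbours, at most 20 tested genes apart on the same chromosome, as are Tmem242 and Tagap1, and Herpud1 and Setd6. Whether counting used strand is not given, so reads of Rab26os and of overlapping transcripts cannot be separated. Hist3h2ba, a histone H2B gene, was listed at 2.93, 3.24 and 2.57 FPKM in WT and at 0 in every PP2Aa-deficient library (limma adjusted p = 0.036). It passed in 6 of the 11 alternatives that tested it, whereas Sfn passed in all 15 and Rab26os in all 12 that tested it. Rab26os and Hist3h2ba met the filter only through the WT libraries. Leaving out any WT library removed both from testing, so their dependence on a WT library was not examined. At an unadjusted limma p under 0.05 there were 893 genes, and other settings called between 0 and 11 higher and between 1 and 12 lower genes.

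Among the genes of smallest p with higher values in PP2Aa-deficient B cells, none of which passed, Alpl, encoding tissue-nonspecific alkaline phosphatase, measured 3.04 ± 0.645 FPKM in WT and 9.95 ± 0.492 in PP2Aa-deficient B cells (SD, n = 3). Pcbd2 measured 3.55 ± 1.83 and 19.9 ± 2.63, Tmem242 13.1 ± 1.52 and 29.9 ± 3.42, and Setd6 0.886 ± 0.161 and 4.25 ± 0.098 FPKM in the same order. Insl3 was under 0.01 FPKM in WT and at 2.47, 2.35 and 2.19 in PP2Aa-deficient libraries, and it overlaps Jak3, as Setd6 overlaps Cnot1. These 5 genes shared a limma adjusted p of 0.0507. Tdp2, encoding a DNA repair enzyme, measured 4.04 ± 0.229 and 9.73 ± 0.319, Plekhf2 9.93 ± 1.37 and 23.2 ± 3.29, Ndnl2 3.82 ± 0.905 and 15.99 ± 5.12, Tagap1 0.548 ± 0.367 and 3.89 ± 0.468, and Bola2 84.4 ± 14.5 and 165 ± 2.44 FPKM. Among the lower genes that did not pass, Sh3bgrl3 measured 1172 ± 92.0 FPKM in WT and 652 ± 70.9 in PP2Aa-deficient B cells, Cpm (carboxypeptidase M) 14.6 ± 1.38 and 5.16 ± 1.55, and Dusp14 7.96 ± 1.78 and 2.54 ± 0.594. Meig1 and Ifitm7 were listed at 0 in every PP2Aa-deficient library and at 1.24 to 2.19 and 1.29 to 1.75 FPKM in WT.

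Genes of plasma cells, the antibody-secreting end stage of the B lineage, were lower as a list in PP2Aa-deficient B cells, with 17 of 18 tested members below WT (camera adjusted p = 2.67e-05). The adjusted p was 0.342 with an estimated correlation. Igj, the joining chain of polymeric antibodies, measured 925 ± 210 FPKM in WT and 282 ± 155 in PP2Aa-deficient B cells (SD, n = 3), a log2 change of -1.82 (SE 0.33). Xbp1, a transcription factor needed for secretion in plasma cells, measured 57.3 ± 7.74 and 37.0 ± 3.81 FPKM, Creld2 74.1 ± 26.1 and 37.9 ± 4.55, and Sdc1, the plasma cell surface marker CD138, 5.56 ± 1.27 and 2.11 ± 1.32. These 4 members fell when adjusted over the list alone, and 0 passed limma over all genes. The unfolded protein response list, which shares 6 tested members with it (Xbp1, Creld2, Hspa5, Edem1, Hsp90b1 and Pdia4), was also lower, with 20 of 26 members below WT (camera adjusted p = 0.00116) and an adjusted p of 0.342 with an estimated correlation. Herpud1, a protein of endoplasmic reticulum quality control, measured 251 ± 22.3 FPKM in WT and 152 ± 18.4 in PP2Aa-deficient B cells. It fell with Xbp1 and Creld2 when adjusted over the list alone, 3 members in all, and 0 passed over all genes.

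Markers of B cell subsets did not all lie on the same side of WT. Marginal zone markers were higher in PP2Aa-deficient B cells, with 12 of 14 members above WT (camera adjusted p = 0.000104), and the adjusted p was 0.43 with an estimated correlation. The sphingosine-1-phosphate receptor gene S1pr3 measured 6.40 ± 0.739 FPKM in WT and 15.3 ± 6.59 in PP2Aa-deficient B cells (SD, n = 3), Cd36 23.5 ± 1.08 and 37.5 ± 10.2, the complement receptor gene Cr2 42.4 ± 8.82 and 62.8 ± 11.4, and Dtx1 22.5 ± 1.54 and 29.7 ± 3.09. Adjusted over the list alone, 0 members passed, as over all genes. Follicular markers were lower in 10 of 12 members (camera adjusted p = 0.0477, and adjusted p = 0.575 with an estimated correlation). The transcription factor gene Bach2, at 11.8 ± 0.915 and 7.38 ± 0.87 FPKM, was the 1 member that fell when adjusted over the list alone, with 0 over all genes, while Satb1 measured 20.6 ± 3.14 and 13.7 ± 1.39. B-1 cell markers were lower in 12 of 17 members (camera adjusted p = 0.0477, and adjusted p = 0.43 with an estimated correlation), with 0 passing adjusted over the list alone or over all genes. Ctla4 measured 4.75 ± 0.66 and 2.18 ± 1.09 FPKM and Bhlhe41 8.51 ± 2.37 and 4.81 ± 1.53. Germinal centre genes were lower in 6 of 8 members (camera adjusted p = 0.0477, and adjusted p = 0.531 with an estimated correlation), with 0 passing adjusted over the list alone or over all genes. This call rested on WT replicate 1, where Rgs13 was at 17.5 FPKM against 2.84 and 3.22 in the other WT libraries and Mef2b at 22.9 against 3.37 and 2.78, and without that library the camera adjusted p was 0.437. It was also lost without PP2Aa-deficient replicates 1 and 3 (camera adjusted p = 0.205 and 0.0536). The follicular call was also lost without WT replicates 2 and 3 and PP2Aa-deficient replicates 1 and 3 (camera adjusted p = 0.113, 0.237, 0.182 and 0.144), and the B-1 call without any library except WT replicate 3 (camera adjusted p from 0.0535 to 0.216).

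Genes of antigen presentation by MHC class II were lower in 10 of 17 members (camera adjusted p = 0.0477, and adjusted p = 0.43 with an estimated correlation). H2-Eb1, which encodes the beta chain of a class II molecule, was at 1575, 1478 and 1533 FPKM in WT and at 199, 1313 and 174 in PP2Aa-deficient replicates 1 to 3. H2-DMa measured 447 ± 66.9 FPKM in WT and 330 ± 12.3 in PP2Aa-deficient B cells (SD, n = 3), H2-Eb2 11.001 ± 2.86 and 6.48 ± 1.09, and Rfx5, a transcription factor of class II genes, 3.60 ± 0.574 and 6.97 ± 0.994. Adjusted over the list alone, 3 members fell and Rfx5 rose, and 0 passed over all genes. The 9 tested H2 members, 5 of them lower, lie on the chromosome of Ppp2r1a. Of the others on it, the class II chain genes H2-Aa and H2-Ab1 had log2 changes of 0.026 and 0.003, and H2-DMb1 and H2-DMb2 of 0.115 and 0.041. Elsewhere 5 of 8 members were lower. For those 8 members camera's p was 0.635, against 0.0181 for all 17 before adjustment. Without PP2Aa-deficient replicate 3 the camera adjusted p was 0.122, and without WT replicates 1 and 2 or PP2Aa-deficient replicate 1 it was 0.143, 0.0716 and 0.0538.

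The list of PP2A subunits and regulators, which holds Ppp2r1a itself, was lower in 19 of 25 members (camera adjusted p = 0.0188, and adjusted p = 0.346 with an estimated correlation). Only Ppp2r1a fell when adjusted over the list alone, and 0 passed over all genes. Ppp2r1b, the beta isoform of the scaffold, measured 5.39 ± 1.22 FPKM in WT and 4.24 ± 0.688 in PP2Aa-deficient B cells (SD, n = 3), and the catalytic subunit gene Ppp2ca 21.4 ± 3.85 and 17.5 ± 2.28. Fry called this list alone among the 29 (adjusted p = 0.0198) and called 0 lists when any 1 library was left out, with no filter, with the filter at 5 FPKM or with a term for Xist. Neither camera nor fry was repeated without Ppp2r1a, which the genotype itself lowers, so these calls cannot be credited to the other subunits. None of the 12 camera calls held with an estimated correlation, a stricter test even for the PP2A list, whose estimate was -0.0262. Without WT replicate 2 or PP2Aa-deficient replicate 1 the camera adjusted p of the PP2A list was 0.0673 and 0.0538.

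Nuclear genes of oxidative phosphorylation were higher in 51 of 72 members (camera adjusted p = 0.00167, and adjusted p = 0.575 with an estimated correlation). Uqcr11, of respiratory complex III, measured 59.03 ± 12.05 FPKM in WT and 109 ± 14.9 in PP2Aa-deficient B cells (SD, n = 3), and Ndufb6, of complex I, 47.0 ± 9.91 and 75.0 ± 10.3. Cytosolic ribosomal protein genes were higher in 60 of 79 members, with a median log2 change of 0.08 (camera adjusted p = 0.0112, and adjusted p = 0.673 with an estimated correlation), and Rps16 measured 1671 ± 46.8 and 2075 ± 43.3 FPKM. The ribosomal list was fixed as a list that follows RNA quality, and its estimated correlation was 0.658. Its call therefore cannot be credited to the genotype. Type I interferon genes were higher in 20 of 23 members (camera adjusted p = 0.00305, and adjusted p = 0.531 with an estimated correlation). The antiviral sensor genes Oas3 and Oas2 measured 0.765 ± 0.007 and 1.503 ± 0.595 FPKM in WT and 1.86 ± 0.121 and 3.65 ± 1.59 in PP2Aa-deficient B cells. In these 3 lists 0 members passed, adjusted over the list alone or over all genes. Without WT replicate 2, the deepest library, the camera adjusted p was 0.268 for oxidative phosphorylation, 0.669 for ribosomal proteins and 0.0835 for interferon genes, and without PP2Aa-deficient replicate 1 it was 0.147 for both of the last. Ribosomal proteins were also lost without WT replicate 3 (camera adjusted p = 0.246).

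**Figure D2:**
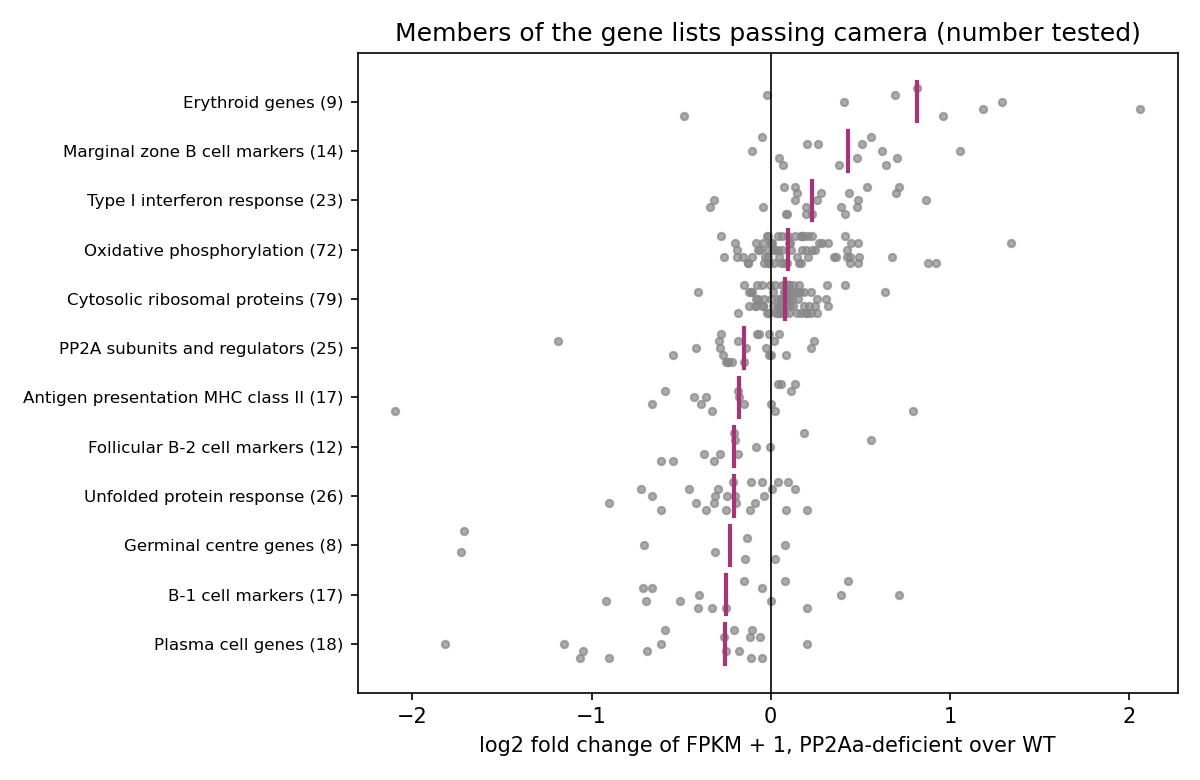
Log2 fold change of FPKM + 1, PP2Aa-deficient over WT (horizontal axis), of each tested member of the 12 gene lists that passed camera at the preset correlation, with the number tested in brackets, a grey point per gene and the list median as a bar. Plasma cell genes had a median of -0.26 and marginal zone markers of 0.43, and single members lay on both sides of 0.

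B cell identity genes were not called (camera adjusted p = 0.128), and Cd79a, a chain of the B cell receptor, measured 1611 ± 83.6 FPKM in WT and 1696 ± 183 in PP2Aa-deficient B cells (SD, n = 3), Ms4a1 (CD20) 330 ± 49.0 and 382 ± 7.62, Pax5 140 ± 8.21 and 120 ± 13.7, and Fcrla 156 ± 8.22 and 102 ± 17.7. B cell receptor signalling genes were not called (camera adjusted p = 0.151), although Malt1, a protease of the NF-kB pathway, at 32.5 ± 2.80 and 48.2 ± 2.48 FPKM, rose when adjusted over the list alone. Immediate early genes (camera adjusted p = 0.0892) and NF-kB targets (0.113) were not called either, with Dusp2 at 106 ± 68.7 and 255 ± 3.12 FPKM and Cd83 at 1403 ± 109 and 1021 ± 89.2. In the cell cycle lists, G1/S (camera adjusted p = 0.0866) and mitosis (0.0826), the centromeric histone gene Cenpa at 27.5 ± 1.71 and 15.4 ± 3.498 FPKM fell when adjusted over the list alone and Cdt1 measured 56.3 ± 4.96 and 44.6 ± 2.43. Among p53 targets (camera adjusted p = 0.151), the death receptor gene Tnfrsf10b at 5.96 ± 0.899 and 2.52 ± 0.336 FPKM fell when adjusted over the list alone. Glycolysis (camera adjusted p = 0.128), with Pfkp at 12.4 ± 0.392 and 8.12 ± 0.649 FPKM, and Toll-like receptor genes (0.206), with Tlr1 at 10.5 ± 1.88 and 14.2 ± 1.06, did not pass. The same held for heat shock genes (camera adjusted p = 0.14, Hspa4l at 1.74 ± 0.638 and 2.99 ± 0.852 FPKM) and MYC targets (0.368, Srm at 15.6 ± 8.58 and 24.7 ± 2.76). Purine metabolism (camera adjusted p = 0.877, Guk1 at 36.9 ± 3.62 and 51.2 ± 3.60 FPKM), the BCL2 family (0.856, Bak1 at 2.61 ± 0.716 and 3.88 ± 0.626) and histones (0.368) did not pass, and their mean and median log2 changes differed in sign. Hist1h2bg, a histone H2B gene, was listed at 0, 3.20 and 5.07 FPKM in WT and at 10.6, 12.9 and 13.2 in PP2Aa-deficient libraries. In all of these lists 0 members passed over all genes.

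Markers of other cells were low in most cases. Macrophage markers were not called (camera adjusted p = 0.0909), but Emr1, the F4/80 antigen, at 8.59, 2.93 and 3.84 FPKM in WT and 0.242, 1.91 and 0.25 in PP2Aa-deficient libraries, and the lipoprotein gene Apoe, at 232 ± 85.5 in WT and 98.8 ± 35.6 (SD, n = 3), fell when adjusted over the list alone. Emr1 lies on the chromosome of Ppp2r1a, as the H2 members do, so its values cannot be read as macrophage content alone. Dendritic cell markers (camera adjusted p = 0.0842) held 1 such member, Cd83, which B cells also express, and T cell markers (0.561) held 0, with Zap70 at 1.26 ± 0.575 and 3.05 ± 0.81 FPKM. Erythroid genes were higher in 7 of 9 members (camera adjusted p = 0.0136, and adjusted p = 0.482 with an estimated correlation). Adjusted over the list alone, 1 member rose, and 0 passed over all genes. Without PP2Aa-deficient replicates 1 and 3 the camera adjusted p of the list was 0.0827 and 0.776. Lists of natural killer, neutrophil, mast cell and eosinophil, and mesothelial and stromal markers had fewer than 5 tested members and were not tested. Of their genes, Il2rb measured 3.53 ± 1.65 and 1.10 ± 0.518 FPKM, Cxcr2 1.40 ± 0.303 and 0.837 ± 0.217, Prg2 31.7 ± 9.54 and 11.3 ± 4.91, and Pecam1, which B cells also express, 36.4 ± 4.66 and 34.1 ± 3.12. Cd5, a marker of B-1a cells, did not exceed 0.246 FPKM in any library.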

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

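The terms for Xist and for relative depth were chosen after seeing the data. Sfn was called lower under every alternative. The plasma cell, marginal zone and unfolded protein response lists were called by camera under all 15 alternatives that refitted the genes, with adjusted p ranging from 4.2e-06 to 0.0016, 1.3e-06 to 0.0028 and 0.00057 to 0.012. All 3 calls were lost with an estimated correlation (adjusted p = 0.342, 0.43 and 0.342), a setting that is stricter even at low correlation. For the unfolded protein response list the estimate, 0.00768, was below the preset 0.01, yet camera's p went from 0.00012 to 0.017. Ppp2r1a kept its direction and an unadjusted limma p under 0.05 under each of the 15. Higher genes numbered 0 in the main setting, 1 with no filter, 3 with the filter at 5 FPKM, 7 with quantile normalization, 4 without the mean-variance trend and 11 with array weights, and between 0 and 4 when each library was left out in turn. Lower genes numbered 3 in the main setting, 5 without the trend, 5 with array weights and between 1 and 12 when each library was left out, with 12 without PP2Aa-deficient replicate 2. Called lists numbered 12 in the main setting, 6 with the filter at 5 FPKM, 7 with median-ratio scaling, between 4 and 14 when each library was left out, 0 with the correlation estimated per list and 1 with fry. The cause of these moves was not tested. Cd79a reversed to -0.017 without PP2Aa-deficient replicate 2 (range over the libraries left out to 0.122), Lyz2 to -0.007 with array weights and to -0.16 and -0.117 without WT replicate 3 and PP2Aa-deficient replicate 3 (range to 0.134), and Notch1 to -0.048 without PP2Aa-deficient replicate 1 (range to 0.253). The direction given by camera reversed, with these mean log2 changes, for heat shock genes (-0.044 without WT replicate 1, range to 0.275), T cell markers (0.017 with no filter), the BCL2 family (-0.035 with no filter, 0.013 without WT replicate 1 and 0.005 without PP2Aa-deficient replicate 3, range to 0.066) and purine metabolism (-0.041 without WT replicate 2 and -0.067 without PP2Aa-deficient replicate 1, range to 0.028). None of these lists was called with all libraries at the settings of the report, and heat shock genes were called without WT replicate 3 (camera adjusted p = 0.00049). The follicular, MHC class II, B-1 and germinal centre lists were called in only 7 of 15, 6 of 15, 4 of 15 and 7 of 14 alternatives. Median-ratio scaling ended all 4 calls and that of erythroid genes (camera adjusted p from 0.053 to 0.0838), and a fit without the trend ended all 4 (from 0.064 to 0.0692). Quantile normalization ended the follicular, B-1 and germinal centre calls (from 0.0519 to 0.0965), array weights the MHC class II, B-1 and germinal centre calls (from 0.0626 to 0.226), the filter at 5 FPKM the interferon, follicular, MHC class II and B-1 calls (from 0.078 to 0.184), no filter the MHC class II call (0.0719) and the Xist term the B-1 call (0.0567). Of 1387 values for 96 other named genes, 1343 stayed on their side of the threshold, 34 moved past it and 5 fell short of it. Only 3 of these genes had passed in the main setting, so most values that stayed were of genes not called in either. The 5 that fell short were all of Hist3h2ba. Of 433 values for 29 lists, 365 stayed, 14 moved past the threshold and 47 fell short of it. Depth near 2000000 fragments in the shallowest library leaves genes of a few FPKM, such as Hist3h2ba, on few fragments.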

Other observations

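All tests of other splits, of neighbouring genes, of a shared chromosome, of replicate 2, of H2 genes, of other cells, of Notch targets and of Rn45s were chosen only after the result was seen, and the tests with a depth term were written before they were run. Hes1, a transcription factor gene switched on by Notch signalling, measured 11.6 ± 6.36 FPKM in WT and 31.4 ± 4.18 in PP2Aa-deficient B cells (SD, n = 3), with a limma adjusted p of 0.195, while Hes5 measured 8.49 ± 1.47 and 6.65 ± 1.76 and Notch1 4.21 ± 0.779 and 4.59 ± 1.14. Hes1 and Dusp2 passed over all genes only without WT replicate 1. In WT replicates 1 to 3 Hes1 was at 18.9, 8.65 and 7.31 FPKM and Dusp2 at 185, 59.4 and 73.1. The purine enzymes Ada and Pnp measured 5.04 ± 1.23 and 4.25 ± 1.84 FPKM in WT and 3.41 ± 0.996 and 2.64 ± 0.323 in PP2Aa-deficient B cells, and neither passed limma. Rn45s was listed at 0 in 3 libraries, and these were the 3 of greatest depth, with 44674, 64287 and 31893 FPKM in the others, as a failed estimate in the deepest libraries would give.

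The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 3 genes and the highest other split 3, so that 2 splits gave as many. It called 12 lists and the highest other split 12, again 2 splits, and it held 893 genes at an unadjusted limma p under 0.05 against 719 in the highest other split, so 1 split, the real one, gave as many.

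Plasma cell genes were lower and marginal zone markers higher in PP2Aa-deficient libraries by camera at the preset correlation, and both calls were lost with an estimated correlation (adjusted p = 0.342 and 0.43). At the preset correlation, a difference in depth is argued against as the whole cause, since with log2 relative depth as a term camera's p was 1.16e-08 for plasma cell genes and 9.56e-05 for marginal zone markers. Depth did go with the first principal component of the libraries, which held 25.9% of the variance. Spearman rho was 0.89 (exact permutation p = 0.033) and Pearson r 0.63 (exact permutation p = 0.14). The second component, with 24.1%, separated the groups, at 19.65, 18.64 and 11.58 in WT and -23, -13.28 and -13.6 in PP2Aa-deficient libraries. Beyond these lists, the depth term was examined only for the unfolded protein response list, so depth stays open for the other called lists. Cells other than B cells in the WT libraries could contribute and stay open, since the lowest adjusted camera p of the T cell, macrophage and dendritic cell lists was 0.0842 and macrophage markers were mixed, with Apoe at 232 ± 85.5 and 98.8 ± 35.6 FPKM but Lyz2 at 11.3 ± 2.48 and 11.3 ± 2.08 and Cd68 at a log2 change of 0.07, while the eosinophil gene Prg2 measured 31.7 ± 9.54 and 11.3 ± 4.91 and the erythroid list was higher in PP2Aa-deficient libraries (camera adjusted p = 0.0136, and adjusted p = 0.482 with an estimated correlation). A hypothesis that Notch target genes move up with the marginal zone markers stays undecided, since Hes1, Hes5 and Notch1 (camera's p was 0.257) were only 3 tested members, under the minimum of 5 for a list, and were chosen after Hes1 had been seen. A different makeup of B cell subsets in the mice, or a different response of each cell, was not tested.

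Ppp2r1a was higher in PP2Aa-deficient replicate 2 than in replicates 1 and 3, at 48.0% of the way from their mean to the WT mean. Wild-type cells or RNA mixed into that library could account for it and stay open, since on 115 genes of other chromosomes, chosen and placed on separate libraries, replicate 2 lay 1.6% of the way with a 95% bootstrap interval over genes from -173.4 to 60.5%, too wide to decide, and the same test put replicate 1 at -71.6% (-909.5 to 646.2%) and replicate 3, the lowest in Ppp2r1a, at 33.1% (-73.5 to 81.5%). The 3 genes called with all libraries lay near the PP2Aa-deficient end, Sfn at 3.2% and Rab26os and Hist3h2ba at 0%. Mixing alone would put them near 48.0%. They were also called without replicate 2 (limma adjusted p = 0.000321, 0.0039 and 0.033), so their calls did not need its values. Passing with replicate 2 included still favours genes that are low in it, and Rab26os and Hist3h2ba rest on values listed at 0. The 12 genes other than Ppp2r1a called without replicate 2 (11 lower and 1 higher) include these 3. The median of the 12 was 58.2%, with 83.9% for the 5 on the chromosome of Ppp2r1a and 36.6% for the 7 not placed on it. Choosing genes on replicates 1 and 3 moves replicate 2 towards WT without any mixing, so positions towards WT decide nothing. The 3 genes at 3.2% and 0% lie against that pull, but they were singled out from the 12 and rest on 1 library, so mixing stays open. Incomplete deletion in that library was not tested.

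Genes near Ppp2r1a held more low p-values than most of the genome, since of its 96 nearest tested neighbours 19.8% had an unadjusted limma p under 0.05 against 9.5% of all genes, the percentile of this share being 98 among windows of the same kind. Other splits gave at most 10.4%, but they also held fewer such genes in all, at most 719 against 893, so their shares start lower. Without PP2Aa-deficient replicate 2, 13 of the 50 genes of smallest p lay on the chromosome of Ppp2r1a where 2.7 would be drawn by share (one-sided Fisher's exact p = 1.7e-06, adjusted p = 5.4e-05 over the 32 tests of this family, lowest p on another chromosome 0.027), but with all libraries 4 of 50 did (Fisher's exact p = 0.29, adjusted p = 0.39), and linked genes are not independent. A candidate explanation, as a hypothesis, is a segment of another strain carried along with the floxed allele. H2-Eb1, the other lower H2 genes of the MHC class II list (camera's p was 0.635 for its 8 members elsewhere) and Vars (8.49, 28.7 and 7.67 FPKM in PP2Aa-deficient replicates 1 to 3 against 28.8 to 30.5 in WT) could belong to it. Rab26os, called with all libraries, and Tmem242 and Tagap1, among the genes of smallest p, lie on that chromosome too, as does the macrophage marker gene Emr1. These genes differed in PP2Aa-deficient replicate 2. There H2-Eb1 (1310 FPKM) and Vars were near WT. Rab26os (0), Tagap1 (4.43), Tmem242 (27.0) and H2-DMa (333) were near the other PP2Aa-deficient libraries. Whether they share a segment was not tested. An effect of PP2Aa loss on all of these genes stays open. Strain segments over the rest of the genome were not decided. The 9 neighbouring pairs among the 50 genes of smallest p were no more than in the highest other split, 11. Over 10000 random draws the median was 5 pairs and the 95th percentile 9 (permutation p = 0.073). Still, 3 of the 9 lie among Sfn (the gene of smallest p), Sh3bgrl3 and Extl1. Among the other pairs are Herpud1 with Setd6 and Alpl with Akr7a5.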
